A study of Mus musculus with 12 samples.

How the data were processed

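The series holds 12 RNA sequencing libraries of transferred TH17 cells sorted from the CNS of RAG2-deficient host mice, 5 WT CXCR6+, 5 WT SLAMF6+, 1 DKO CXCR6+ and 1 DKO SLAMF6+. Per the labels' protocols, 1000 living cells per library were sorted, full-length cDNA was made by a modified SMART-Seq2 protocol, Nextera XT libraries were prepared and sequenced as paired reads on a NextSeq 500. Such libraries do not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart. The authors deposited expected counts per gene symbol, made with STAR 2.7.7a and RSEM 1.3.3 on the mm10 build per the submitters' processing notes, in a single table of whole numbers. The annotation used, read filtering and the handling of reads that match several genes are not given in the sources used here. The deposited expected counts were taken as unnormalised estimates rounded to whole numbers.

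The table had 47359 gene rows, no duplicated symbol and 12 columns, each matched to 1 sample by its label. Of the symbols, 41368 (87.3%) matched a single gene of GENCODE M21, the source of coordinates (GRCm38), GC content and transcript lengths. Library totals ran from 6818658 to 11635037 counts, and the number of genes with counts from 21160 to 26242. At these totals the floor of 3 counts, used wherever a group held 0 counts of a gene, was taken over all libraries of the group. Ratios with 1 to 3 counts carry 95% exact Poisson intervals, and shares of single libraries carry 95% exact binomial intervals.

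Groups were taken from the labels, and the fixed choices named here were made before the data were examined. The tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, genes kept by filterByExpr with the groups given (21565 of the single libraries, 23248 of the sums), the quasi-likelihood test, and Benjamini-Hochberg adjustment with a threshold of 0.05. All 4 groups entered a single fit with no block (common dispersion 0.396, 8 residual degrees of freedom), from which came CXCR6+ against SLAMF6+ in WT, DKO against WT in each subset, and the interaction of genotype and subset. A second fit compared the sum of both DKO libraries with the 5 sums of the WT libraries of the same number. The spread came from the WT libraries, and a DKO library was assumed to vary like them. The DKO pair was compared as log2 ratios with a prior count of 2 and no test. Counts of T cell receptor segments are given as shares of all Trbv or Trav counts.

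Gene lists fixed beforehand, 36 in number, covered T cell programmes, metabolism, receptor signalling and markers of other cells. Of these, 31 with at least 5 measured genes were tested with limma's camera (version 3.58.1) with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Summed CPM of marker lists describe other cells. Genes are named by a fixed rule: the targeted and sort genes; for WT the 10 highest and 10 lowest fold changes among called genes of at least 20 CPM with the same direction in all 5 pairs of libraries of the same number, without receptor and immunoglobulin segments and unnamed gene models; for DKO against WT the 8 highest and 8 lowest among called genes of at least 20 CPM with the DKO value outside the WT range; for the interaction the 5 smallest p in each direction; up to 4 members of each list by p; and called genes within 5 Mb of Il17a, of which examples are given. Some genes that the rule selects are not reported here.

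The same steps were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. In CXCR6+ against SLAMF6+ in WT (18817 genes run), 37% of the 2-fold and 68% of the 4-fold changes were recovered. For DKO against WT these shares were 12% and 47% in CXCR6+ (18703 genes), 10.0% and 33% in SLAMF6+ (18691 genes) and 18% and 49% in the sums (19183 genes). For the interaction they were 2% and 16% (18701 genes). False calls numbered 6, 4, 1, 7 and 0 in that order. A list of genes shifted by a known amount was called in all 5 comparisons, with 1 other list called in the interaction. The simulated genes varied independently, so this does not test the preset correlation for lists whose members vary together.

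Alternatives replaced the scaling (DESeq2 1.42.0 size factors), the test (DESeq2's Wald test, limma-voom), the filter (none; at least 10 CPM in 5 libraries), the genes entering the library size (without receptor, mitochondrial and ribosomal protein genes), the samples in the fit, the threshold (at least 2-fold), the block (replicate number, fixed or random) and the libraries (each WT library or replicate number left out). Alternatives added after seeing the data kept only protein-coding genes of at least 300 nt, thinned all libraries to the smallest total, removed a spline of 5 degrees of freedom on GC content and transcript length (fitted on 7375 genes; 90.5% of tested genes had both values), added a term for libraries with mt-Ts1 at 0 counts, joined the block with the GC and length offsets, or left out 3 WT libraries. The labels do not say that replicate numbers name a shared animal, so the main fit assumed no pairing, although the sums and the naming rule for WT joined libraries of the same number. Sequencing reads were not used here and were not aligned again. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.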

Results

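RNA was sequenced from TH17 cells that had been transferred into RAG2-deficient mice, which form no T or B cells of their own, and recovered from the central nervous system (CNS). They were taken when experimental autoimmune encephalomyelitis, a mouse model of multiple sclerosis, was at its height. The donor cells carried the 2D2 label, a transgenic T cell receptor against myelin oligodendrocyte glycoprotein, and were wild type (WT) or lacked both Il17a and Il17f (double knockout, DKO). Living cells were sorted as CXCR6+ or SLAMF6+, with 1000 cells per library. There were 5 WT CXCR6+ libraries, 5 WT SLAMF6+ libraries, 1 DKO CXCR6+ library and 1 DKO SLAMF6+ library. The library totals were 6818658 to 8710148 counts in WT CXCR6+, 8134987 to 11635037 in WT SLAMF6+, 8552216 in DKO CXCR6+ and 8285134 in DKO SLAMF6+. Levels are given as CPM, counts scaled to library totals adjusted with TMM factors, as the mean ± SD over the 5 libraries of a WT subset, and as the single value of a DKO library, for which no replicate exists. The labels do not say whether replicates came from separate animals, so each p measures only the spread between these samples.

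Il17a and Il17f, the targeted cytokine genes, were present in all WT libraries and near 0 in both DKO libraries. Il17a (chromosome 1, 20730905 to 20734496 in the GRCm38 build) stood at 345 ± 104 CPM in WT CXCR6+ and 339 ± 85.8 CPM in WT SLAMF6+ (n = 5 each). The DKO CXCR6+ library held 0 counts of Il17a, at least 994-fold lower against a floor of 3 counts, and the DKO SLAMF6+ library held 3 counts (0.434 CPM). Il17f (chromosome 1, 20777146 to 20790617) stood at 42.5 ± 20.5 CPM in WT CXCR6+ and 85.1 ± 34.0 CPM in WT SLAMF6+, with 1 count in each DKO library (0.116 and 0.145 CPM). Between the WT subsets neither cytokine passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (Il17a log2 fold change 0.03, adjusted p 0.959; Il17f log2 fold change -1.004, adjusted p 0.0548). The Il17f difference passed with the replicate number as a fixed block (-1.08, adjusted p 0.0401) or a random block (-1.12, adjusted p 0.026). It also passed without replicate 3 of both subsets (-1.26, adjusted p 0.045) and without WT CXCR6+ replicate 3 (-1.23, adjusted p 0.0292). The other settings in which it passed were DESeq2's Wald test, limma-voom, protein-coding genes alone and a fit without receptor, mitochondrial and ribosomal protein genes (adjusted p 0.0111 to 0.0488). Over all alternatives its adjusted p ran from 0.0111 to 0.567. Il17a passed only with offsets for GC content and transcript length (0.76, adjusted p 0.0372; 0.0372 to 1.0 over all alternatives).

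Cxcr6, the chemokine receptor gene of the sort (chromosome 9, 123806475 to 123811760), stood at 26.3 ± 16.3 CPM in WT CXCR6+ and 16.1 ± 2.93 CPM in WT SLAMF6+. That difference did not pass the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (log2 0.71, adjusted p 0.251). WT CXCR6+ replicate 3 held only 4.34 CPM of Cxcr6. Without that library the log2 fold change was 0.98 (adjusted p 0.0145), and without replicate 3 of both subsets it was 1.02 (adjusted p 0.0268), within a range of 0.0145 to 0.641 over all alternatives. Slamf6, the other sort gene (chromosome 1, 171917515 to 171953170), was lower in WT CXCR6+ than in WT SLAMF6+ (3.30 ± 1.46 against 8.42 ± 2.25 CPM; log2 -1.35, adjusted p 0.0047). Both sort genes were far higher in the DKO libraries. Cxcr6 reached 382 CPM in DKO CXCR6+ and 162 CPM in DKO SLAMF6+ (log2 3.86 and 3.33 over WT), and Slamf6 reached 75.8 and 259 CPM (log2 4.51 and 4.94 over WT).

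**Figure D1:**
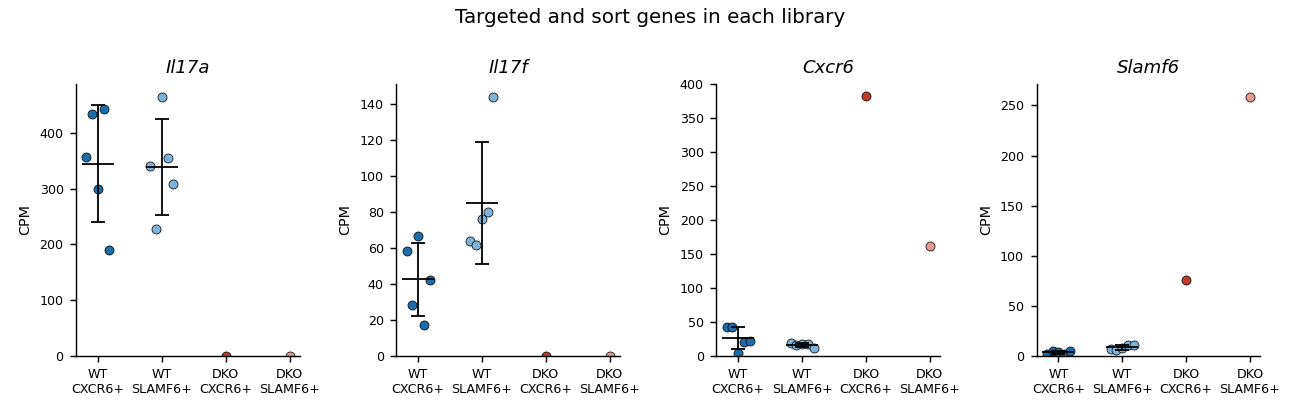
CPM (vertical axis, linear, from 0) of Il17a, Il17f, Cxcr6 and Slamf6 in each of the 12 libraries by group, with 1 point per library and bars for the mean ± SD of the 5 WT libraries. The DKO points lie at or near 0 for Il17a and Il17f and above all WT points for Cxcr6 and Slamf6.

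T cell receptor transcripts differed between the genotypes as well. Trbv16, the gene segment of the Vβ11 chain used by the 2D2 receptor (chromosome 6, 41151740 to 41152230), made up 99.61 to 99.81% of all Trbv counts in the 10 WT libraries. It made up 9.96% in DKO CXCR6+ (1276 of 12812 Trbv counts, 95% exact binomial interval 9.45 to 10.49%) and 6.51% in DKO SLAMF6+ (764 of 11729, 6.07 to 6.98%). Trbv13-2 was the most frequent segment in both DKO libraries, at 21.6% and 19.0%, and the effective number of Trbv segments was 10.2 in each DKO library against 1.00 to 1.01 in WT. Trav9n-3 and Trav9d-3, near-identical copies of the Vα3.2 family, share reads that cannot be assigned with certainty. Together they made up 85.4 to 90.9% of Trav counts in WT, 0.57% in DKO CXCR6+ (0.43 to 0.76%) and 0.12% in DKO SLAMF6+ (0.06 to 0.22%). Such intervals, and the floors of 3 counts, cover counting error only. Donor sex genes also differed: Xist, the X inactivation transcript, stood at 183 ± 24.5 CPM in WT CXCR6+ and 51.6 ± 7.35 CPM in WT SLAMF6+ and at 0 counts in both DKO libraries. The Y-linked gene Ddx3y was at 0 counts in all 10 WT libraries and at 36.3 and 36.1 CPM in the DKO CXCR6+ and SLAMF6+ libraries.

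**Figure D2:**
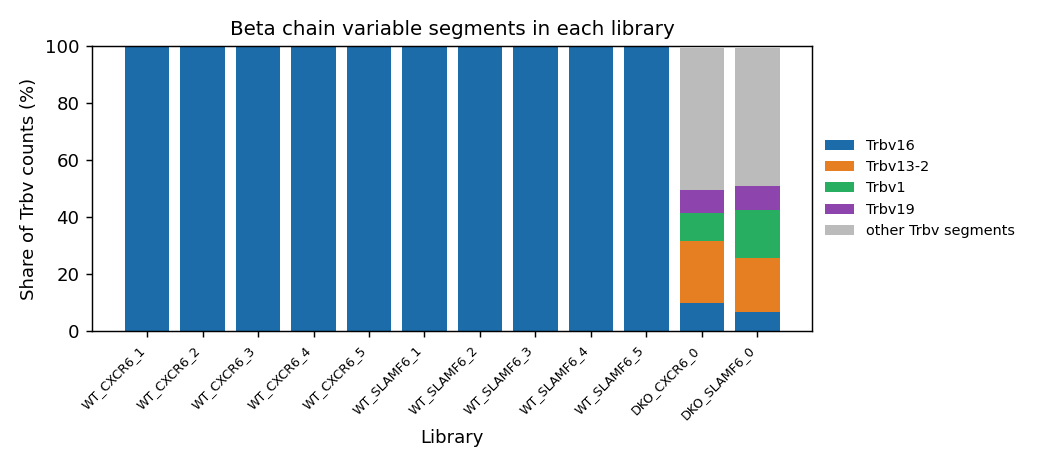
Share of Trbv counts (vertical axis, percent) taken by Trbv16, Trbv13-2, Trbv1, Trbv19 and all other Trbv segments in each library (horizontal axis). Trbv16 fills at least 99.61% of each WT bar and 9.96% and 6.51% of the DKO bars.

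RNA composition separated the WT subsets without overlap. Mitochondrial genes took 15.5 ± 2.01% of counts in WT CXCR6+ and 3.18 ± 1.23% in WT SLAMF6+ (n = 5 each). Ribosomal protein genes took 11.4 ± 0.628% and 21.9 ± 0.596%, and the nuclear transcript Malat1 took 1.06 ± 0.121% and 0.218 ± 0.0281%. The DKO CXCR6+ and SLAMF6+ libraries lay between them, with 7.45% and 8.56% mitochondrial, 17.8% and 16.7% ribosomal protein and 0.663% and 0.594% Malat1 counts. Haemoglobin genes took 11.9% of the counts of the DKO SLAMF6+ library. Spearman correlations across genes, which are not independent replicates, were 0.890 to 0.906 within WT CXCR6+, 0.910 to 0.933 within WT SLAMF6+, 0.863 for the DKO pair and 0.769 to 0.788 between a DKO library and the WT libraries of its subset. The DKO CXCR6+ library correlated no less with the WT SLAMF6+ libraries (0.778 to 0.793) than with those of its own subset (0.771 to 0.788).

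**Figure D3:**
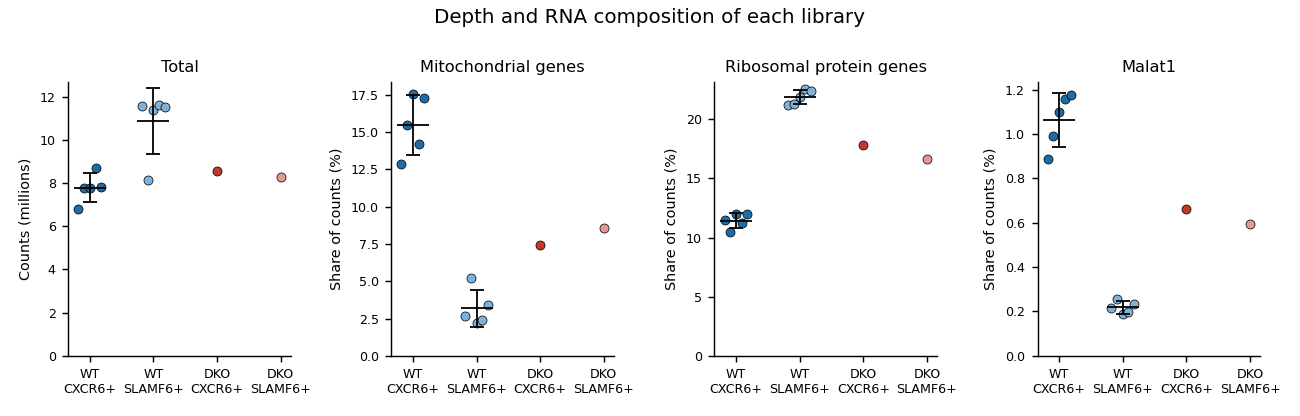
Total counts (M) and the share of counts (percent) from mitochondrial genes, ribosomal protein genes and Malat1 in each library by group, with bars for the mean ± SD of the 5 WT libraries. The WT CXCR6+ points lie at 12.9 to 17.6% mitochondrial counts and the WT SLAMF6+ points at 2.20 to 5.24%.

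In the WT libraries, CXCR6+ were compared with SLAMF6+ TH17 cells, the subsets described elsewhere as effector-like and stem-like. The RNA composition given above parted with the sort, so the differences below cannot be assigned to the sort alone. Lower in WT CXCR6+ cells were 17 of 19 glycolysis genes (camera adjusted p 1.11e-09), 21 of 23 nuclear genes of oxidative phosphorylation (1.7e-13) and 24 of 32 proliferation genes (8.92e-06), calls lost with an estimated correlation (adjusted p = 0.283 to 0.377). Bnip3, a hypoxia-induced mitophagy gene of the glycolysis list, stood at 111 ± 11.03 CPM in CXCR6+ and 328 ± 26.1 CPM in SLAMF6+ (log2 -1.56, adjusted p 5.69e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 5 each). Higher in CXCR6+ were Dusp2, a phosphatase gene induced by receptor signalling (78.3 ± 12.3 against 21.5 ± 2.40 CPM, log2 1.87) and the insulin-like hormone gene Insl3 (76.1 ± 29.1 against 4.65 ± 0.613 CPM, log2 4.03). Itgb7, which encodes the β7 integrin chain, was higher too (104 ± 10.4 against 45.7 ± 7.43 CPM, log2 1.18). In all, 7179 of 21565 tested genes (33.3%) passed, 3363 higher and 3816 lower in CXCR6+, and 2841 of them differed at least 2-fold (1812 higher, 1029 lower). The balance of directions turned with DESeq2's size factors (3614 higher, 3596 lower) or Wald test (4239, 4040), a filter of 10 CPM (2843, 2463) and only the groups compared in the fit (3986, 3379).

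Among genes of at least 20 CPM that kept 1 direction in all 5 pairs of WT libraries with the same number, the 10 largest increases in CXCR6+ included mitochondrial and nuclear RNAs. The transcript mt-Nd3 rose from 177 ± 102 to 827 ± 64.7 CPM and mt-Atp8 from 2227 ± 829 to 8547 ± 1019 CPM. The log2 increase of mt-Nd1 was 1.86, and Malat1 rose from 2458 ± 341 to 9162 ± 1258 CPM (log2 1.90). These 4 moved with the shares of mitochondrial and Malat1 counts given above. The others were Insl3, Dusp2, Phxr4 (log2 2.04), AY036118 (log2 1.96), and the small nucleolar RNAs Snord47 and Snord35a. These snoRNAs stood at 91.1 ± 83.1 and 81.7 ± 86.6 CPM in CXCR6+ and at 0 counts in SLAMF6+, at least 1462-fold and 1312-fold higher. WT CXCR6+ replicate 1 held 237.8 and 233.94 CPM of them and the others 33.56 to 65.94 and 29.28 to 71.0 CPM, so these limits would be lower without it. Both lie inside longer host genes, so their counts are uncertain, and limma-voom ended the Snord35a call (adjusted p 0.066; 3.51e-21 to 0.066 over all alternatives). Of 1001 genes under 150 nt, 156 to 225 had counts in the WT CXCR6+ libraries and 114 to 143 in WT SLAMF6+. The limits for such short genes may thus not measure expression alone. The 10 largest decreases were led by pseudogenes, whose counts are uncertain because near-identical copies exist: Rbpj-ps3 (log2 -2.63), Pgam1-ps2 (-2.29), Rps15a-ps5 (-2.09), Rpl34-ps1 (-1.91), Rps12-ps3 (-1.88) and Rps10-ps2 (-1.85). The other decreases were Dpm1, a mannosyltransferase subunit (17.99 ± 5.55 against 69.6 ± 9.81 CPM), and the interferon-induced membrane gene Ifitm1 (22.3 ± 9.64 against 84.0 ± 32.4 CPM), followed by Plac8 (26.996 ± 6.39 against 99.97 ± 9.65 CPM) and the cytokine gene Il4 (19.3 ± 11.3 against 69.5 ± 23.3 CPM, log2 -1.85). Offsets for GC content and transcript length ended the calls of Il4 (-0.97, adjusted p 0.1; 0.000117 to 0.154 over all alternatives) and Rps15a-ps5 (adjusted p 0.104; 0.00446 to 0.118). The Rps15a-ps5 call also ended without replicate 1 (0.0539) or replicate 4 (0.0767) of both subsets.

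Of the fixed gene lists, 5 passed camera's set test with a preset correlation in WT CXCR6+ against SLAMF6+, and all 5 lost their call with an estimated correlation. Fold changes in WT also rose with transcript length (Spearman 0.433 over 7674 genes). Only the glycolysis median was taken again with offsets for GC content and length. With these offsets 5371 of the 7179 WT calls stayed. The glycolysis list had 17 of 19 measured members lower and 1 higher (17 and 1 adjusted over the list alone; median log2 -0.87; adjusted p 1.11e-09, and adjusted p = 0.377 with an estimated correlation). Examples were the glycolytic enzyme gene Pgk1 (981 ± 75.3 against 1981 ± 80.4 CPM) and Mif (1507 ± 117 against 3447 ± 206 CPM), whose processed pseudogenes make its count uncertain. The oxidative phosphorylation list, which holds nuclear genes of the respiratory chain, had 21 of 23 members lower (22 adjusted over the list alone; median -0.80, adjusted p 1.7e-13, and adjusted p = 0.283 with an estimated correlation). Examples were the ATP synthase gene Atp5c1 (198 ± 11.63 against 412 ± 25.1 CPM) and the cytochrome oxidase gene Cox4i1 (log2 -0.92). These nuclear genes were lower in the same libraries in which the mitochondrially encoded share was higher and the ribosomal protein share lower. The proliferation list had 24 of 32 members lower and 3 higher (26 and 5 adjusted over the list alone; median -0.51, adjusted p 8.92e-06, and adjusted p = 0.377 with an estimated correlation). Examples were the replication licensing gene Mcm6 (116.5 ± 14.4 against 227 ± 16.8 CPM) and Stmn1 (125 ± 14.5 against 231 ± 20.5 CPM). The cholesterol synthesis list had 13 of 20 members lower and 2 higher (14 and 2 adjusted over the list alone; median -0.63, adjusted p 0.000103, and adjusted p = 0.377 with an estimated correlation). Fdps stood at 251 ± 29.0 against 457 ± 37.6 CPM. The interferon list had 11 of 29 members lower and 1 higher (11 and 2 adjusted over the list alone; median -0.48, adjusted p 0.004, and adjusted p = 0.283 with an estimated correlation). Examples were Ifi27l2a (1071 ± 122 against 2580 ± 205 CPM) and Gbp2 (72.5 ± 15.1 against 215 ± 23.2 CPM).

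T cell programmes were mixed between the WT subsets. Of 23 early receptor activation genes 10 rose in CXCR6+ and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p 0.129). Dusp5 stood at 50.5 ± 4.94 against 22.7 ± 1.76 CPM. The TH17 list had 1 of 21 members higher and 6 lower (the same counts adjusted over the list alone; camera adjusted p 0.129), among the latter Batf (log2 -0.73), Hif1a (-0.53) and the cytokine gene Il24 (-1.15). The TH1 and encephalitogenic list had 2 of 24 members higher and 8 lower (4 and 8 adjusted over the list alone; adjusted p 0.396). Examples were the receptor genes Il2rb (-0.90) and Il12rb2 (-0.92). The stem or memory-like list had 3 of 24 members higher and 6 lower (3 and 6 adjusted over the list alone; adjusted p 0.76; median 0.04, mean -0.09, test direction down). The lymphoid homing receptor gene Ccr7 stood at 351.5 ± 78.8 against 759.7 ± 42.7 CPM and the transcription factor gene Lef1 at 62.4 ± 4.18 against 115 ± 16.2 CPM. Il13, a type 2 cytokine gene, was higher in CXCR6+ (79.5 ± 17.3 against 43.9 ± 5.94 CPM), while Il4 was lower. Of the markers of other cells, 5 of 12 MHC class II and dendritic cell genes were lower in CXCR6+ (5 adjusted over the list alone; adjusted p 0.0842). An example was Cd74 (log2 -1.65). Myeloid genes went both ways, 3 of 18 higher and 3 lower (3 and 3 adjusted over the list alone; adjusted p 0.882), with the microglial gene Tmem119 (2.88 ± 1.57 against 18.01 ± 3.42 CPM) among the lower. Aldoc and Cnp of the astrocyte and oligodendrocyte lists were lower as well (log2 -1.19 and -1.04). The T cell receptor complex genes Cd3g (-1.01) and Cd3e (-0.54) were also lower, and the CD4 T cell list had 4 of 10 members lower and 1 higher (5 and 1 adjusted over the list alone; adjusted p 0.101).

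The libraries also split by a mitochondrial tRNA gene, largely but not wholly along the sort. This gene, mt-Ts1, was listed at 0 counts in WT CXCR6+ replicate 1 and in WT SLAMF6+ replicates 1, 3, 4 and 5, and was present in all other libraries. Within the WT libraries at 0, 1 CXCR6+ against 4 SLAMF6+, 3385 genes passed, and within the others, 4 against 1, 2413 passed, with the spread taken from a joint fit of all libraries. The glycolysis list had a median log2 difference of -0.95 and -0.66 within these parts, and oxidative phosphorylation had -0.92 and -0.65. The medians were -0.63 and -0.37 for proliferation, -0.63 and -0.51 for cholesterol synthesis and -0.63 and -0.36 for the interferon list. Fewer members of each of these lists, glycolysis and oxidative phosphorylation included, passed there than in the pooled test. The DKO CXCR6+ library differed in 5851 genes from the 4 WT CXCR6+ libraries that, like it, had mt-Ts1 counts, in the same fit. In SLAMF6+ only 1 WT library had such counts, so no number of calls is given. Against that library, 100% of the genes called against all 5 WT SLAMF6+ libraries, of which it is 1, kept their direction. With a term for this split in the fit, 5128 genes passed in WT (7179 without it), and the median log2 difference was -0.87 for the glycolysis list and -0.78 for oxidative phosphorylation.

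**Figure D4:**
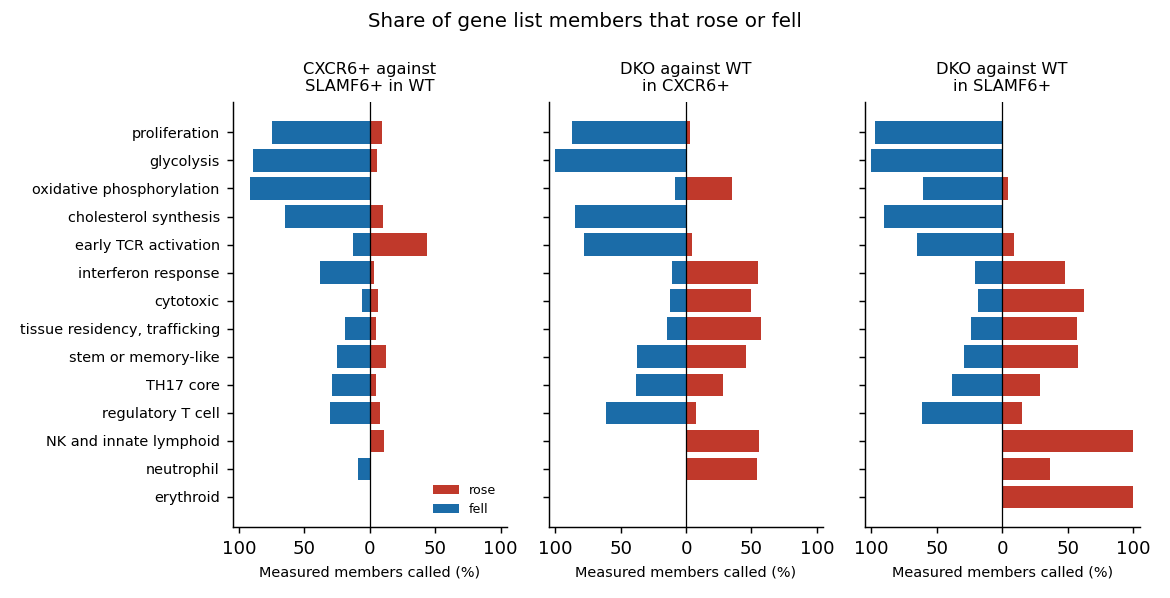
Share of the measured members of each fixed gene list (rows) that passed the test (horizontal axis, percent), with members that rose to the right and members that fell to the left, in the 3 comparisons of single subsets. All 19 glycolysis genes fell in both comparisons of DKO with WT, and 17 of 19 fell in WT CXCR6+ against SLAMF6+.

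In CXCR6+ cells, the effector-like subset, the DKO library was set against the 5 WT libraries, from which it also differed in receptor segments and donor sex genes. Besides Il17a and Il17f, 18 of 23 early receptor activation genes, all 19 glycolysis genes and 28 of 32 proliferation genes were lower in the DKO library. The camera adjusted p values were 4.78e-09, 3.73e-16 and 4.61e-15, and each list had adjusted p = 0.0618 with an estimated correlation. Il2ra, the high-affinity interleukin 2 receptor gene, stood at 23.0 CPM against 952 ± 71.0 CPM (log2 -5.37, adjusted p 1.11e-08, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Irf4 stood at 5.20 against 213 ± 13.0 CPM and the costimulatory receptor gene Tnfrsf9 at 4.16 against 410.2 ± 65.2 CPM. Higher in the DKO library were the trafficking genes Cxcr3 (217 against 13.2 ± 2.28 CPM, log2 4.04), Itgb7 (932 against 104 ± 10.4 CPM) and Klf2, a quiescence factor (56.4 against 0.598 ± 0.212 CPM, log2 6.53). With 1 DKO library, assumed to vary like the WT libraries, 6199 of 21565 genes (28.7%) passed, 2767 higher and 3432 lower, and 4611 of them differed at least 2-fold.

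Among genes of at least 20 CPM outside the WT range, the 8 largest increases in DKO CXCR6+ were all of genes with 0 counts in the 5 WT CXCR6+ libraries. The neutrophil alarmin genes S100a8 and S100a9 stood at 498 and 426 CPM (at least 7490-fold and 6418-fold higher). They were followed by Cd7, a lymphocyte surface gene (136 CPM, at least 2054-fold), the histamine receptor gene Hrh4 (40.1 CPM, at least 604-fold) and the Y-linked Ddx3y. The small RNA genes Snord12 (136.5 CPM), Mir3098 and Mir6360, which lie inside longer genes and whose counts are uncertain, made up the rest. The 8 largest decreases were of genes with 0 counts in DKO CXCR6+. They were Il17a, Xist, the retinoic acid binding protein gene Crabp2 (466 ± 116 CPM in WT, at least 1343-fold lower), Serpinf1 (263 ± 45.8 CPM, at least 759-fold) and 4 cytokine genes. The chemokine genes among these were Ccl3 (234 ± 184 CPM, at least 674-fold) and Ccl4 (206 ± 109 CPM, at least 593-fold), and the others were Il24 (221 ± 55.7 CPM, at least 637-fold) and Il21 (221 ± 23.3 CPM, at least 636-fold). Of Ccl3, WT CXCR6+ replicate 1 held 561.02 CPM and the others 121 to 176 CPM, so its limit would be lower without that library. Limma-voom ended the calls of Il17a (adjusted p 0.178), Il17f (0.334), Ccl3 (0.403), Ccl4 (0.38) and Crabp2 (0.0724), within a range of 3.47e-11 to 0.406 over all alternatives. It also moved the split of calls from 2767 higher and 3432 lower to 4125 higher and 2433 lower.

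Most members of the glycolysis, proliferation, cholesterol synthesis and early receptor activation lists fell in DKO CXCR6+, and the calls of these lists were lost with an estimated correlation. All 19 glycolysis genes fell (19 adjusted over the list alone; camera adjusted p 3.73e-16, and adjusted p = 0.0618 with an estimated correlation). Examples were the glycolytic enzyme gene Tpi1 (67.6 against 947 ± 77.1 CPM) and Hk2 (7.40 against 94.7 ± 6.20 CPM). Proliferation had 28 of 32 members lower and 1 higher (29 and 1 adjusted over the list alone; adjusted p 4.61e-15, and adjusted p = 0.0618 with an estimated correlation). The mitotic kinase gene Aurkb stood at 7.86 against 86.5 ± 11.59 CPM and Top2a at 36.4 against 182.5 ± 14.3 CPM. Cholesterol synthesis had 17 of 20 members lower (17 adjusted over the list alone; adjusted p 4.44e-09, and adjusted p = 0.0883 with an estimated correlation). Fdft1 stood at 12.8 against 51.0 ± 6.02 CPM. Early receptor activation had 18 of 23 members lower and 1 higher (18 and 1 adjusted over the list alone; adjusted p 4.78e-09, and adjusted p = 0.0618 with an estimated correlation). Egr2 stood at 2.78 against 63.0 ± 6.72 CPM. The regulatory T cell list had 8 of 13 members lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p 0.000191, and adjusted p = 0.0637 with an estimated correlation). The inhibitory receptor gene Ctla4 stood at 8.09 against 218 ± 30.8 CPM. These genes were lower in a library whose receptor segments and donor sex genes also differed from WT.

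In the lists of tissue entry, cytotoxicity and the interferon response more members rose than fell in DKO CXCR6+, and the calls of all of them were lost with an estimated correlation. Tissue residency and trafficking had 12 of 21 members higher and 3 lower (12 and 3 adjusted over the list alone; camera adjusted p 0.000347, and adjusted p = 0.189 with an estimated correlation). Examples were the integrin gene Itga4 (183 against 7.73 ± 1.79 CPM) and the sphingosine phosphate receptor gene S1pr4 (232 against 24.3 ± 3.80 CPM). Cytotoxic genes had 8 of 16 members higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p 0.00234, and adjusted p = 0.0746 with an estimated correlation). Ctsw stood at 476 against 40.2 ± 9.44 CPM and Klrd1 at 96.0 against 4.39 ± 1.71 CPM. The interferon list had 16 of 29 members higher and 3 lower (18 and 3 adjusted over the list alone; adjusted p 0.000129, and adjusted p = 0.0618 with an estimated correlation). Isg20 stood at 30.2 against 2.35 ± 0.471 CPM and Zbp1 at 72.6 against 22.8 ± 1.37 CPM. Stat2 was lower (log2 -1.59). The nuclear oxidative phosphorylation genes had 8 of 23 members higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p 0.0477, and adjusted p = 0.51 with an estimated correlation). The TH1 and encephalitogenic list had 11 of 24 members higher and 7 lower (13 and 7 adjusted over the list alone; adjusted p 0.0477, and adjusted p = 0.454 with an estimated correlation). Its median of 0.58, also with members at 0 counts set at their bound, and its test pointed up while its mean was -0.91. The TH17 list moved both ways, 6 of 21 members higher and 8 lower (7 and 8 adjusted over the list alone; adjusted p 0.873; median 0.96 and 0.38 with members at 0 counts at their bound, mean -0.28). Hif1a was lower (38.8 against 328 ± 23.2 CPM) and the IL-17C receptor subunit gene Il17re was higher (91.4 against 7.82 ± 1.11 CPM). The IL-17 receptor signalling list, which also holds Il17re, had 4 of 12 members higher and 4 lower (4 and 4 adjusted over the list alone; adjusted p 0.873).

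Markers of other cells moved with the DKO CXCR6+ library as well. Neutrophil genes had 6 of 11 members higher and none lower (6 adjusted over the list alone; camera adjusted p 0.000129, and adjusted p = 0.0499 with an estimated correlation). An example was the granule gene Camp (81.8 CPM, 4 counts over the 5 WT libraries). Natural killer and innate lymphoid genes had 5 of 9 members higher (5 adjusted over the list alone; adjusted p 0.000256, and adjusted p = 0.0499 with an estimated correlation). An example was the signalling adaptor gene Fcer1g (25.1 against 0.422 ± 0.415 CPM). Astrocyte genes had 4 of 5 members lower (4 adjusted over the list alone; adjusted p 0.00392, and adjusted p = 0.0618 with an estimated correlation). The gap junction gene Gja1 stood at 0.462 against 38.4 ± 5.88 CPM and Aldoc at 2.43 against 60.01 ± 8.66 CPM. The T cell genes did not move together: Cd3e was higher (578 against 160 ± 14.2 CPM). Lower were Trbv16 (147.5 against 14093 ± 2986 CPM), Trbc2 (1797 against 23251 ± 4278 CPM) and Trac (543 against 2610 ± 564 CPM), while Trbv13-2 was higher (320 against 2.50 ± 1.34 CPM). Trbc1, the other beta chain constant gene, was not lower (1000 against 818 ± 116 CPM).

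In SLAMF6+ cells, the stem-like subset, the DKO library against the 5 WT libraries had 15 of 23 early receptor activation genes and all 19 glycolysis genes lower, with haemoglobin transcripts beside them. The camera adjusted p were 1.04e-05 and 1e-19, with adjusted p = 0.12 and adjusted p = 0.0647 with an estimated correlation. Il2ra stood at 14.6 against 807 ± 25.5 CPM (adjusted p 1.8e-08, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Lower as well were Irf4 at 2.17 against 243 ± 20.6 CPM, Tpi1 at 47.2 against 1976 ± 106 CPM and the homing receptor gene Ccr7 at 61.1 against 759.7 ± 42.7 CPM. Higher were Klf2 (56.8 against 0.357 ± 0.116 CPM), Itga4 (186.5 against 5.33 ± 1.43 CPM) and Cxcr3 (229 against 11.59 ± 2.21 CPM). With the single DKO library again assumed to vary like the WT libraries, 6697 of 21565 genes (31.1%) passed, 2913 higher and 3784 lower, and 5137 of them differed at least 2-fold.

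The 8 largest increases in DKO SLAMF6+ were of haemoglobin genes and mitochondrial tRNA genes. Hba-a2 and Hba-a1 stood at 64941 and 14629 CPM, Hbb-bs and Hbb-bt at 51691 and 12022 CPM, and the reads of each of these pairs of near-identical copies cannot be assigned to 1 gene with certainty. The tRNA genes mt-Tk (455 CPM, at least 7300-fold higher), mt-Ta (329 CPM, at least 5288-fold), mt-Tm (223 CPM, at least 3586-fold) and mt-Tw (128 CPM, at least 2063-fold) were at 0 counts in WT SLAMF6+. Of those WT libraries, 4 of 5 also had mt-Ts1 at 0, which the DKO library did not. Of 1001 genes under 150 nt, 114 to 143 had counts in the WT SLAMF6+ libraries and 189 in DKO SLAMF6+. The limits for such short genes may thus not measure expression alone. All of the 8 largest decreases were of genes at 0 counts in DKO SLAMF6+. They began with Crabp2 (539.7 ± 65.0 CPM in WT, at least 1242-fold lower), Il24 (491 ± 69.4 CPM, at least 1129-fold) and the metallothionein gene Mt2 (340.4 ± 20.9 CPM, at least 783.5-fold). The others were the protease inhibitor gene Timp1 (178 ± 41.5 CPM, at least 409-fold), the TNF receptor family gene Tnfrsf8 (152 ± 8.83 CPM), the osteopontin gene Spp1 (99.4 ± 32.9 CPM), Rgs16 (85.4 ± 10.1 CPM) and the matrix gene Lum (78.6 ± 9.42 CPM). The mt-Tm call (adjusted p 0.0494) ended in 12 of the 15 fits that left out 1 library or 1 replicate number (0.0432 to 0.0924), ended with a term for the mt-Ts1 split (log2 11.19, adjusted p 0.307) and over all alternatives ran from 1.77e-06 to 0.307. Limma-voom ended 9 calls, those of Il17a (0.109), Il17f (0.27), Crabp2, Mt2, Spp1, Rgs16, Lum, mt-Ta and mt-Tm (0.0506 to 0.724; 2.5e-22 to 0.724 over all alternatives). It moved the split from 2913 higher and 3784 lower to 4504 higher and 2772 lower, and a filter of 10 CPM to 2463 higher and 2224 lower.

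All 19 glycolysis genes fell in DKO SLAMF6+ (19 adjusted over the list alone; camera adjusted p 1e-19, and adjusted p = 0.0647 with an estimated correlation). Pgk1 stood at 174.5 against 1981 ± 80.4 CPM, Hk2 at 2.46 against 70.3 ± 4.63 CPM and Bnip3 at 5.50 against 328 ± 26.1 CPM. Proliferation had 31 of 32 members lower (31 adjusted over the list alone; adjusted p 3.45e-18, and adjusted p = 0.0647 with an estimated correlation). The spindle gene Tpx2 stood at 4.78 against 66.8 ± 4.73 CPM. Cholesterol synthesis had 18 of 20 members lower (18 adjusted over the list alone; adjusted p 3.23e-11, and adjusted p = 0.0802 with an estimated correlation). Fdft1 stood at 17.8 against 88.8 ± 3.90 CPM. Early receptor activation had 15 of 23 members lower and 2 higher (15 and 2 adjusted over the list alone; adjusted p 1.04e-05, and adjusted p = 0.12 with an estimated correlation). Tnfrsf9 stood at 4.78 against 699 ± 84.8 CPM. Oxidative phosphorylation had 14 of 23 members lower and 1 higher (18 and 1 adjusted over the list alone; adjusted p 4.63e-05, and adjusted p = 0.187 with an estimated correlation). An example was Atp5b (log2 -0.76). The haemoglobin share of 11.9% stood in the same library.

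Stem or memory-like genes had 14 of 24 members higher and 7 lower in DKO SLAMF6+ (14 and 7 adjusted over the list alone; camera adjusted p 0.0157, and adjusted p = 0.17 with an estimated correlation). The lymphocyte egress receptor gene S1pr1 stood at 177 against 41.7 ± 4.17 CPM beside the lower Ccr7. Tissue residency and trafficking had 12 of 21 members higher and 5 lower (12 and 5 adjusted over the list alone; adjusted p 0.00339, and adjusted p = 0.25 with an estimated correlation), including Itgb7 at 755 against 45.7 ± 7.43 CPM. Cytotoxic genes had 10 of 16 members higher and 3 lower (11 and 3 adjusted over the list alone; adjusted p 0.0029, and adjusted p = 0.0802 with an estimated correlation). The granzyme gene Gzmk stood at 67.9 CPM against 0 counts (at least 1091-fold higher) and Gzmb at 31.3 against 529.9 ± 88.2 CPM. The interferon list had 14 of 29 members higher and 6 lower (15 and 6 adjusted over the list alone; adjusted p 0.0861). Isg20 stood at 147 against 6.49 ± 2.06 CPM. The TH17 list had 6 of 21 members higher and 8 lower (8 and 8 adjusted over the list alone; adjusted p 0.425; median 0.80, also with members at 0 counts at their bound, mean -0.44, test direction down). There were 3 counts of Il21 (0.434 against 225 ± 18.6 CPM, a WT to DKO ratio of 177 to 2512) and 1 count of the IL-23 receptor gene Il23r (35.2 ± 4.07 CPM in WT, ratio 43.6 to 9595).

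The erythroid and natural killer lists kept their calls with an estimated correlation in the same library, and those of other cell types did not. All 6 erythroid genes rose (6 adjusted over the list alone; camera adjusted p 2.75e-06, and adjusted p = 0.0273 with an estimated correlation). An example was the haem synthesis gene Alas2 (455 against 1.74 ± 1.09 CPM). All 9 natural killer and innate lymphoid genes rose (9 adjusted over the list alone; adjusted p 5.8e-05, and adjusted p = 0.0416 with an estimated correlation). MHC class II and dendritic cell genes had 7 of 12 members higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p 0.0029, and adjusted p = 0.147 with an estimated correlation). H2-Aa stood at 312.5 against 8.12 ± 1.99 CPM and Cd74 at 350.3 against 95.6 ± 16.8 CPM. Myeloid genes had 10 of 18 members higher and 3 lower (12 and 3 adjusted over the list alone; adjusted p 0.00594, and adjusted p = 0.179 with an estimated correlation). Neutrophil genes had 4 of 11 members higher (5 adjusted over the list alone; adjusted p 0.00227, and adjusted p = 0.0802 with an estimated correlation). S100a8 stood at 26.2 CPM and S100a9 at 45.6 CPM.

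The DKO comparisons of the CXCR6+ and the SLAMF6+ subset, which share no library, called many of the same genes. Shared in both were 1429 higher genes, against 373.8 for independent lists, and 2279 lower genes, against 602.2, while 222 genes passed in opposite directions. Both comparisons came from the same fit, and genes with little spread pass more easily in each. Overlap above that of independent lists is thus partly built in. Of all tested genes, 28.7% passed in CXCR6+ and 31.1% in SLAMF6+. Of the 43 tested genes within 5 Mb of Il17a other than the targeted cytokine genes, 6 passed in CXCR6+ and 16 in SLAMF6+. Among these neighbours, the replication gene Mcm3 was lower (log2 -1.23 and -2.04) and Smap1 was higher (log2 1.11 and 1.23) in DKO CXCR6+ and SLAMF6+.

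Summing both subsets of each number gave 1 DKO sum and 5 WT sums, which asks how the genotypes differ with both subsets joined. Counts were added without balancing depth, so the subsets weigh differently in each sum. CXCR6+ and SLAMF6+ totals were 8.55 and 8.29 M in DKO and, for example, 6.82 and 11.59 M in WT replicate 1. The sums are thus not free of the subset difference. Il17a stood at 0.19 CPM (3 counts) against 343 ± 57.7 CPM, a WT to DKO ratio of 616 to 8732, and Il17f at 0.127 CPM (2 counts) against 63.5 ± 20.6 CPM, a ratio of 139 to 4133. Cxcr6 (281 against 21.1 ± 8.46 CPM, log2 3.73, adjusted p 0.000858) and Slamf6 (155 against 5.92 ± 1.33 CPM, log2 4.71, adjusted p 2.7e-05) were higher in the DKO sum by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 7322 of 23248 genes (31.5%) passed, 3077 higher and 4245 lower, with the DKO sum assumed to vary like the WT sums. Limma-voom moved this split to 4934 higher and 3015 lower.

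The largest changes of the summed libraries were, but for Snord104, among those named in the single subsets. Higher were the haemoglobin genes, uncertain between their copies, S100a8 (285 CPM, at least 8945-fold higher), S100a9 (254 CPM, at least 7984-fold), mt-Tk and Snord12. At 0 counts in DKO were Crabp2 (503 ± 39.3 CPM in WT, at least 2644-fold lower), Il24, Mt2, Timp1, Tnfrsf8, Xist, Snord104 and Rgs16. Limma-voom ended the calls of Il17a, Il17f, Il24, Rgs16, Snord104 and Timp1 (adjusted p 0.0691 to 0.639; 1.8e-34 to 0.639 over all alternatives). The proliferation list had 31 of 32 members lower (31 adjusted over the list alone; camera adjusted p 1.71e-19, and adjusted p = 0.0371 with an estimated correlation), with the mitotic genes Aurka (log2 -3.41) and Ccnb1 (-3.86). Early receptor activation had 17 of 23 members lower and 3 higher (17 and 3 adjusted over the list alone; adjusted p 4.23e-08, and adjusted p = 0.0451 with an estimated correlation), with Tnfrsf9 (-6.99) and Irf4 (-5.89). All 19 glycolysis genes were lower (19 adjusted over the list alone; adjusted p 5.01e-18, and adjusted p = 0.103 with an estimated correlation). Klf2 (6.89), Cxcr3 (4.16) and Itgb7 (3.53) were higher.

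The interaction asks whether the difference between CXCR6+ and SLAMF6+ cells was itself another in DKO than in WT. Some genes of sugar breakdown and respiration, lower in CXCR6+ than in SLAMF6+ in WT, stood nearer to each other in the DKO libraries. The mitochondrial shares did so too: 7.45% and 8.56% in DKO CXCR6+ and SLAMF6+ against 15.5 ± 2.01% and 3.18 ± 1.23% in WT, with ribosomal protein and Malat1 shares alike. Gapdh stood at 394 and 405 CPM in DKO CXCR6+ and SLAMF6+, and at 1203 ± 164 and 3098 ± 113 CPM in WT (log2 difference 1.32, adjusted p 0.00547, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its many pseudogenes leave its count uncertain. The glycolysis list had 10 of 19 members higher in this difference (14 adjusted over the list alone; median 0.76, camera adjusted p 4.29e-08, and adjusted p = 0.34 with an estimated correlation). An example was Tpi1 (1.58). Oxidative phosphorylation had 14 of 23 members higher (15 adjusted over the list alone; median 0.75, adjusted p 1.02e-10, and adjusted p = 0.306 with an estimated correlation). Examples were Atp5c1 (1.02) and Sdhd (1.51). The interaction differences fell with transcript length (Spearman -0.276 over 7674 genes), and the medians of both lists were not taken with offsets for length. Stem or memory-like genes had 5 of 24 members lower (7 lower and 1 higher adjusted over the list alone; adjusted p 0.0283, and adjusted p = 0.34 with an estimated correlation). Examples were the receptor genes Il6ra (-4.67) and Cd27 (-1.14). All 6 erythroid genes were lower (6 adjusted over the list alone; adjusted p 0.00177, and adjusted p = 0.151 with an estimated correlation).

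Among the leading interaction genes by p were the interferon-induced Ifitm2, the kinase gene Pbk and the protease gene Ide on the higher side. Ifitm2 stood at 549 and 224 CPM in DKO CXCR6+ and SLAMF6+ and at 233 ± 13.3 and 568 ± 44.5 CPM in WT (adjusted p 0.000154, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). On the lower side were the ubiquitin-conjugating enzyme gene Ube2l6 (log2 difference -3.17), Cd200 (-2.10), the small nucleolar RNA Snora57, whose count is uncertain inside a longer gene, Mgarp and Sapcd2. Limma-voom ended the calls of Mgarp, Sapcd2 and Snora57 (adjusted p 0.0613 to 0.0654; 2.05e-05 to 0.0654 over all alternatives). In all, 2221 of 21565 genes (10.3%) passed, 1372 higher and 849 lower, with each DKO library assumed to vary like the WT libraries. With genes under 10 CPM left out, 45.3% of the calls were higher against 61.8%. Il17a (adjusted p 0.375), Il17f (adjusted p 1.0), Cxcr6 (0.53, adjusted p 0.905) and Slamf6 (-0.42, adjusted p 0.823) did not pass.

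Between the DKO CXCR6+ and SLAMF6+ libraries themselves, with 1 library each and no replicate check, 6570 genes differed more than 2-fold at a prior count of 2, 3005 higher and 3565 lower in CXCR6+. Across genes, which are not independent replicates, these log2 ratios had a Pearson correlation of 0.041 and a Spearman correlation of 0.069 with the WT fold changes. Of the 7179 genes called in WT, 3949 (55.0%) had the same sign.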

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

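The tests of RNA quality, of too few receptor reads and of other clones, and the analysis with GC and length offsets, were chosen only after the results they measure were seen.

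WT CXCR6+ cells had lower glycolysis genes than WT SLAMF6+ cells, with a list median of -0.87 (95% bootstrap interval over its members -1.03 to -0.62). Without receptor, mitochondrial and ribosomal protein genes in the library size the median was -0.896 (-1.06 to -0.64). With offsets for GC content and transcript length it was -0.814 (-1.08 to -0.69). Both lie below the bound of -0.4 set for scaling or GC and length as the whole cause. The first fit kept TMM scaling, so it tests only the weight of those gene classes and leaves other faults of scaling open. The intervals treat list members as independent, although their estimated correlation was 0.44. Lower RNA quality or yield of the CXCR6+ libraries stays open, since their lowest mitochondrial share was 12.9% against a highest of 5.24% in WT SLAMF6+, and the sort and the RNA composition cannot be told apart. A difference in metabolism between the subsets is the biological explanation, and it stays open beside RNA quality. Of 126 possible splits of the 10 WT libraries, 100 were run. Only 1 of these, the real one, gave as many called genes (7179, against at most 3 in the others). A random division of the libraries is thus an unlikely source of that count. The other splits mixed the subsets, which widened their spread, so their counts do not measure calls without a subset difference. The split test cannot part the sort from RNA composition or the mt-Ts1 split.

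The segments of the receptor that the label 2D2 names were scarce in the DKO libraries. With 11729 Trbv counts in the lower of the DKO libraries, too few receptor reads is excluded as an explanation. T cells of other clones than 2D2 in the DKO libraries may account for it: Trbv16 made up at most 9.96% of Trbv counts there and many other segments were present. Donor cells from DKO mice without the receptor transgene and a wrong label are candidate explanations that no table parts. Y-linked Ddx3y was at 36.3 and 36.1 CPM in the DKO libraries and at 0 counts in WT, and Xist the other way round, and the labels name no donor sex.

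The DKO and WT libraries differed in 6199 genes in CXCR6+ and 6697 in SLAMF6+. A lone WT library against the other 4 of its group called at most 3 genes. Spread of the size seen between WT libraries is thus excluded as the whole cause. The WT libraries also supplied the spread of the test, and 1 DKO library per subset cannot show how DKO libraries vary. Shared calls of the subsets exceeded those of independent lists at least 3.78 times. That ratio cannot decide on erythroid RNA, since both comparisons came from 1 fit and the same genes pass more easily in each. Haemoglobin made up 11.9% of counts in DKO SLAMF6+ and was near 0 in DKO CXCR6+. Erythroid RNA is thus excluded as the whole cause of the 6199 calls in CXCR6+, and for SLAMF6+ it stays open. The loss of Il17a and Il17f is the biological explanation named by the design, and it stays open beside the other clones, the donor sex transcripts and anything else particular to the single DKO library of each subset, which coincide with the genotype.

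The difference between the subsets differed between the genotypes by the interaction term in 2221 genes and in 4 lists: stem or memory-like genes (adjusted p 0.0283), glycolysis (4.29e-08), oxidative phosphorylation (1.02e-10) and erythroid genes (0.00177) by camera with a preset correlation. All 4 lists lost their call with an estimated correlation (adjusted p = 0.34, 0.34, 0.306 and 0.151). Of the named genes, the adjusted p of edgeR's quasi-likelihood test were 0.000154 for Ifitm2, 0.000281 for Pbk, 0.000607 for Ide, 0.000296 for Ube2l6, 0.000403 for Snora57, 0.000473 for Cd200, Mgarp and Sapcd2, 0.00125 for Tpi1, 0.00547 for Gapdh, 0.00302 for Atp5c1, 0.00355 for Sdhd, 0.000718 for Il6ra, 0.00512 for Cd27, 0.00179 for Hba-a1 and 0.00215 for Alas2.

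In 18 of 276 groups of 5 libraries tested, 1 library stood apart from the other 4 by Dixon's criterion, and chance flags about 1 in 20 groups. In WT SLAMF6+, replicate 2 had a total of 8.13 M counts (others 11.41 to 11.64 M), summed CD4 T cell markers of 32454 CPM (36993 to 38799), 19.654 CPM of Dusp5 (23.0 to 24.0) and 26.954 CPM of S1pr4 (34.9 to 36.6). The CD4 marker sum is largely receptor RNA: Trbc2 averaged 30021 CPM in that group, and Cd4 298 CPM. Replicate 5 had 241.72 CPM of summed B cell markers (39.87 to 47.86), 144.2 CPM of Il17f (61.63 to 79.83), 4893.4 CPM of mt-Nd1 (2847 to 3309), 16.715 CPM of Rps15a-ps5 (37.9 to 39.9), 2932.1 CPM of Ifi27l2a (2403 to 2551) and 366.83 CPM of Ccl3 (166 to 207). Replicate 1 had 217.54 CPM of Ctla4 (163 to 177). In WT CXCR6+, replicate 1 had 237.8 CPM of Snord47 (33.56 to 65.94), 233.94 CPM of Snord35a (29.28 to 71.0) and 561.02 CPM of Ccl3 (121 to 176). Replicate 3 had 36.783 CPM of Mgarp (27.8 to 30.3), replicate 4 had 6.47 CPM of summed gamma delta T cell markers (2.40 to 3.51), and replicate 5 had 85.908 CPM of Phxr4 (61.3 to 66.3) and 13.388 CPM of Rps10-ps2 (8.33 to 9.36).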

How the results depend on the processing

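The alternatives with protein-coding genes alone, thinned libraries, GC and length offsets, the mt-Ts1 term, the block joined with offsets and 3 libraries left out were chosen after seeing the data; the others were planned. Genes over 2-fold between the DKO libraries numbered 6570 at a prior count of 2, 7327 at 0.5 and 5284 at 5; filters for values other than counts did not apply. Targeted and sort genes in single subsets aside, 201 of 223 named gene results kept direction and side of the threshold in every setting. Of 5665 comparisons 5610 were the same and 55 weaker (20 with limma-voom, 14 with the random block), and none reversed. Most of these genes were named for small p or large fold changes in the same libraries, so the tally was partly fixed beforehand. The cause was not tested in any case below unless fewer genes or a stricter threshold made the change. Called genes with 1 library or replicate number left out numbered 5826 to 6949 for WT, 5614 to 6203 for DKO CXCR6+, 5954 to 6885 for DKO SLAMF6+, 1687 to 2347 for the interaction and 6459 to 7125 for the sums. A fold of at least 2 left 2841 genes in WT, and a filter of 10 CPM left 4614 in the sums. With an estimated correlation camera called 0 lists in WT (3 at an unadjusted p under 0.05), 2 in DKO CXCR6+, 2 in DKO SLAMF6+, 0 in the interaction (3 unadjusted) and 3 in the sums; fry called 16 in WT and 11 in the interaction, against 5 and 4 with the preset correlation.

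Between the WT subsets, Il17a (0.03, not called) was reversed with limma-voom (-0.0103), no filter (-0.00766), the block (-0.00167), the random block (-0.0103) and without 3 libraries (-0.15), passed with GC and length offsets (0.76, adjusted p 0.0372), and ran from -0.18 to 0.21 with 1 replicate left out. Il17f (-1.004) passed with DESeq2's Wald test (-0.95), limma-voom (-1.12), without receptor, mitochondrial and ribosomal protein genes (-1.03), with the block (-1.08), the random block (-1.12) and protein-coding genes (-0.91), and ran from -1.26 to -0.72 with 1 replicate left out; Cxcr6 ran from 0.45 to 1.02. Against WT, limma-voom and the random block ended the calls of Il17a in DKO CXCR6+ (-12.48 in both) and SLAMF6+ (-9.36) and of Il17f (-7.76 and -8.55), fitted values that depend on the prior count.

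The counts did not show whether the replicate numbers pair the libraries. Deviations of same-numbered WT libraries correlated at 0.029, 0.0075, -0.0092, 0.0243 and -0.0117, and 2 of 5 libraries correlated best with their own number. Such weak values leave open whether a number names a shared animal. The replicate block gave 6944 genes in WT and 1554 in the interaction, and 6225 in WT with GC and length offsets; the random block (limma-voom) gave 7986 in WT, 6563 and 7263 for DKO against WT in CXCR6+ and SLAMF6+ and 2268 in the interaction. With a term for mt-Ts1, 5128, 5980, 5208 and 1692 genes passed in the same order. Many changes could be missed: in simulations of WT, 37% of 2-fold changes were recovered, and 2% in the interaction.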

Other observations

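The checks of sampling noise and of GC content and transcript length were chosen only after the results were seen; the lists were fixed in advance.

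More members fell than rose in the stress, cytokine, checkpoint, follicular helper and type 2 lists in the DKO libraries. Those lists that passed camera with a preset correlation lost their call with an estimated one. The heat shock and dissociation list had 12 of 19 members lower and 3 higher in DKO CXCR6+ (12 and 4 adjusted over the list alone; camera adjusted p 0.00909, and adjusted p = 0.155 with an estimated correlation) and 10 lower and 2 higher in DKO SLAMF6+ (10 and 2 adjusted over the list alone; adjusted p 0.0029, and adjusted p = 0.12 with an estimated correlation). In WT it had 8 members lower and 1 higher in CXCR6+ (8 and 2 adjusted over the list alone; adjusted p 0.129). The list of other cytokines had 11 of 26 members lower and 5 higher in DKO CXCR6+ (13 and 5 adjusted over the list alone; adjusted p 0.0411, and adjusted p = 0.404 with an estimated correlation) and 10 lower and 3 higher in DKO SLAMF6+ (10 and 3 adjusted over the list alone; adjusted p 0.0495, and adjusted p = 0.38 with an estimated correlation). Checkpoint genes went both ways in both DKO libraries, 6 of 18 higher and 9 lower in each (6 and 9 adjusted over the list alone; adjusted p 0.118 and 0.154). Follicular helper genes had 5 of 11 members lower in DKO CXCR6+ (6 adjusted over the list alone; adjusted p 0.0202, and adjusted p = 0.215 with an estimated correlation) and 3 lower and 1 higher in DKO SLAMF6+ (3 and 1 adjusted over the list alone; adjusted p 0.272). Type 2 genes had 4 and 5 of 10 members lower (4 and 5 adjusted over the list alone; adjusted p 0.4931 and 0.159). Il13 stood at 0 counts in DKO CXCR6+ (at least 229-fold lower).

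Transcripts of other cells differed between libraries in level. Summed CPM of neutrophil markers were 1065 in DKO CXCR6+ and 103 in DKO SLAMF6+, against 0.57 to 4.06 in the WT libraries. Summed natural killer and innate lymphoid markers were 1179.6 and 1147 against 226 to 450.2 CPM, and gamma delta T cell markers 59.2 and 37.7 against 2.40 to 6.47 CPM. The gamma delta list did not pass camera in DKO CXCR6+ or SLAMF6+ (adjusted p 0.0984 and 0.147). Of its 5 measured members, 3 rose and 1 fell in CXCR6+, and 1 rose and 1 fell in SLAMF6+ (4 and 1, and 3 and 1, adjusted over the list alone). Summed MHC class II and dendritic cell markers were 271 CPM in DKO CXCR6+, 1600.1 CPM in DKO SLAMF6+, 306 ± 39.7 CPM in WT CXCR6+ and 622 ± 30.9 CPM in WT SLAMF6+. Erythroid markers summed to 143757 CPM in DKO SLAMF6+ and to 0.97 to 3.58 CPM in WT. Astrocyte markers went the other way, at 107 ± 10.97 and 221 ± 9.01 CPM in WT CXCR6+ and SLAMF6+. They stood at 3.82 and 3.91 CPM in the DKO libraries. Most of the WT CXCR6+ sum came from Aldoc and Gja1. Aldoc was lower in the same comparisons as the glycolysis list, so the sum alone does not show astrocyte RNA. Oligodendrocyte markers were 72.6 ± 5.23 and 138 ± 10.5 CPM in WT and 255 and 243 CPM in DKO. In the oligodendrocyte list 2 of 5 members rose in each DKO comparison (2 and 3 adjusted over the list alone; camera adjusted p 0.0363 and 0.0465; adjusted p = 0.119 and adjusted p = 0.153 with an estimated correlation), with a median of 1.06 and a mean of -0.03 in CXCR6+. The sort was for living cells by surface markers, and nothing in the labels says how other cells were gated out.

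No pair of replicates agreed within sampling noise (chi-square per degree of freedom of 11.007 to 49.9), as a library deposited more than once would. Fold changes in WT correlated across genes with GC content (Spearman 0.129) and transcript length (0.433) over 7674 genes, which are not independent replicates. The interaction differences correlated with them at -0.105 and -0.276.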
